A study of Mus musculus with 72 samples.

How the data were processed

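The arrays were Agilent mouse oligonucleotide microarrays with 44397 spots, hybridised to Cy5-labelled sample and a Cy3-labelled common reference. Per the submitters' processing notes the scans were read with Agilent Feature Extraction 10.7.3.1. The headers of the 20 arrays in the second array set name version 10.5.1.1 instead. Signals and local backgrounds in the scanner files are intensities, and the LogRatio column is a log10 ratio of sample to reference per the file headers. The table of values in the series record equals that column at each of 44397 spots (largest difference 0), so it was put on the log2 scale and used as an alternative source.

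Median signals were background-corrected against median local backgrounds with normexp and an offset of 50, then normalised within each array by loess with control spots (1377) given no weight. The design had assumed mean signals, which the files of the first array set do not hold, and median signals were used for all arrays. Spots marked as non-uniform or population outliers were left out, 171 to 834 per array, and spots of a probe were averaged. Of 39429 probes, 26055 were named by RefSeq accession, 3195 by current symbol, 930 by a synonym, and 9249 stayed under the name in the scanner file. A gene was represented by the probe with the highest mean intensity over the arrays of the planned fit. In the alternatives that leave out arrays this probe was at first chosen anew, which let a gene change probe, and it was then held. That rule was set after the leave-out values had been seen.

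The fits used limma 3.58.1 with statmod 1.5.0 in R 4.3.3, empirical Bayes moderation, two-sided tests and Benjamini-Hochberg adjustment over all genes of a contrast, with an adjusted p below 0.05 called. Adjusted p values of single genes are limma's throughout. A gene entered when its sample channel was well above background on at least 3 arrays of the fit and each group had at least 2 values. The gate fit used the 35 non-irradiated vehicle arrays with array set as a covariate (28090 genes). The treatment fit used the 48 sorted arrays of replicates 1 to 3 in 16 groups (26932 genes). Another fit used means over the 4 populations of 12 mice (26889 genes), taking samples with one replicate number and treatment as one animal, which the labels do not state. The array of pooled epithelium was not part of any fit.

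In the first array set each slide of sorted cells held the 4 treatments of one population and replicate number, and another slide held unsorted replicates 1 to 3 and the pool, so array position and treatment were tied in sorted cells. In the second set each population lay on a slide of its own. Across genes, deviations from group means of arrays on one slide had a mean correlation of 0.327 (59 of 72 pairs above 0.1), and those of one replicate number in other populations of 0.311. Pairs of different slides had a mean of -0.160. Values with slide (treatment fit) or replicate number (gate fit and mouse means) as a block are therefore given where they change a call or move a count by more than 1.5 times. No pair of arrays was identical. The lowest correlation between 2 arrays was -0.386 (Low vehicle 5, Negative vehicle 6). Since the dyes are stated and these gates differ in opposite ways from the pool, no direction was changed.

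Gene lists (38) were written from general knowledge before the data were examined, as were the fits, the thresholds and most alternatives. The lists described in the text, the clock genes and 5 further alternatives that leave out replicates or weight arrays were chosen afterwards. Each list with at least 5 measured members was tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 38 lists of a contrast. Camera with the correlation estimated per list, and fry, were alternatives. Of 950 tests of a list in a contrast 351 were called with the preset and 11 with the estimated correlation, and fry called 203. Genes named in the text are a panel of 20 marker genes, the 6 highest and 6 lowest called genes without overlap between groups, up to 4 members of a described list, and members that oppose their list. Each was refitted in every alternative except Ccn1 and Sesn1, named as opposing their lists, Angptl4 in the mouse means, Ifit1, and the genes of the closing observations. Some genes that meet this rule are not reported. Where a group was not well above background a fold is given as a lower bound. Array coordinates are not printed, because the array and the reference table use different mouse genome builds.

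Known changes were planted in simulated values to test the procedure. These values were independent normal noise with each gene's residual spread, without the correlation among genes, slides or mice in the data. They therefore cannot test how such correlation affects the list calls. Of 100 genes changed 2-fold, 94 were recovered between High and Low, 78 for irradiation in High and 88 for the mouse means, and at 4-fold 100, 95 and 96. Unchanged genes called numbered 16, 6 and 12. A list shifted by 0.5 log2 units was called in each of the 3 fits, with 1 other list called in the mouse means and 0 in the rest. Over all genes, no other scaling moved the median difference of a contrast by more than 0.1 log2 units. The largest shift was -0.082, for High minus Low. The scalings compared each centre or equalise the arrays, so these medians were held small in advance. They do not show that other results are unaffected by scaling.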

Results

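Gene expression was measured on two-colour oligonucleotide microarrays in epithelial cells of the mouse jejunum sorted by a Sox9-EGFP reporter. Sox9 is a transcription factor of the intestinal crypt, and the reporter mice carry EGFP under its regulatory sequences on a bacterial artificial chromosome. Flow cytometry separated cells with no EGFP (Negative) and cells with 3 rising levels of EGFP (Sublow, Low and High). Mice received no irradiation or a single abdominal dose of 14 Gy, and a mini-pump then delivered vehicle or insulin-like growth factor 1 (IGF1, 10 mg/ml in the pump) until tissue was taken at 5 days. Each of the 4 populations from non-irradiated vehicle mice came from 7 animals, and each of the other 12 combinations of population and treatment from 3 animals. Unsorted epithelium of 7 non-irradiated vehicle mice and 1 array of pooled unsorted epithelium completed the 72 arrays. Every sample was labelled with Cy5 and set against one Cy3 reference, a pool of unsorted epithelium from non-irradiated mice, so each value is the log2 ratio of the sample to that pool. Between 56% and 86.4% of the probes on an array were well above background in the sample channel. The number of arrays in a group sets the precision of each value.

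Sox9 itself rose with EGFP. In the 7 non-irradiated vehicle mice its log2 ratio to the reference was -0.24 ± 0.546 (SD, n = 7) in Negative cells, 1.17 ± 0.259 in Sublow, 2.17 ± 0.252 in Low and 3.24 ± 0.396 in High cells, beside 0.11 ± 0.259 in unsorted epithelium. Lgr5, the receptor that marks cycling crypt base stem cells, was highest in Low cells at 2.63, against 1.31 in Sublow, 0.38 in High and -0.72 in Negative cells. Chga, the secretory granule protein of enteroendocrine cells, reached 5.22 in High cells, and Dclk1, a tuft cell marker, reached 3.17 there. Fabp1, a fatty acid binding protein of absorptive enterocytes, was at 0.01 in Negative cells and at -4.79 in Low cells. Mki67, a proliferation marker, was positive in Sublow (0.92) and Low (0.82) cells and negative in High cells (-0.63).

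**Figure D1:**
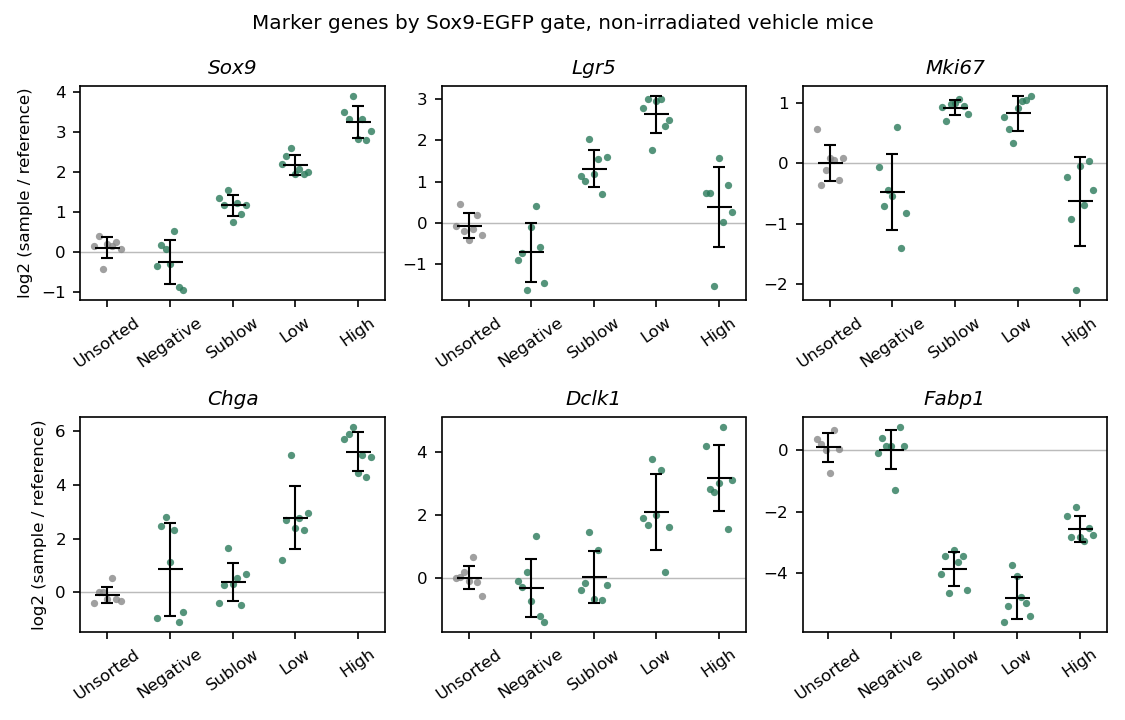
Log2 ratio of sample to reference (vertical axis) for 6 marker genes in unsorted epithelium and the 4 Sox9-EGFP gates (horizontal axis) of non-irradiated vehicle mice, with 1 point per mouse (n = 7) and bars for mean and SD. Sox9 climbs from -0.24 in Negative to 3.24 in High cells, whereas Lgr5 is highest in Low cells at 2.63.

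Sublow cells differed from Negative cells by the loss of the absorptive programme and by higher proliferation and stem cell transcripts (n = 7 mice each). All 30 measured absorptive enterocyte genes fell, with the drug-metabolising Cyp3a11 at -4.77 ± 0.35 (log2 difference ± SE), the vitamin B12 receptor Cubn at -4.24 ± 0.32, the glucose transporter Slc2a2 at -4.02 ± 0.37 and Fabp2 at -3.92 ± 0.23. Of 34 genes of the G2 and M phases 33 rose and 1 fell, with the spindle checkpoint kinase Bub1 at 1.89 ± 0.22 and the spindle motor Kif11 at 1.72 ± 0.20, and of 32 S phase genes 30 rose and 2 fell, with the replicative helicase subunits Mcm4 at 1.81 ± 0.18 and Mcm2 at 1.74 ± 0.18. Of 19 active stem cell genes 16 rose and 2 fell. Olfm4 rose by 2.02 ± 0.29 and Lgr5 by 2.03 ± 0.31, while Igfbp4, a binding protein of IGF, was among those that fell, by 0.35 ± 0.14. The Igfbp4 call was lost without replicate 2, 4, 6 or 7 (adjusted p = 0.105, 0.161, 0.0949 and 0.0777). Of 34 ribosome biogenesis genes 33 rose, with the pseudouridine synthase Dkc1 at 1.62 ± 0.17 and Utp20 at 1.43 ± 0.14, and Noc3l fell by 2.27 ± 0.15. All 20 markers of T cells and intraepithelial lymphocytes fell as well, Gzma by 2.81 ± 0.31 and Cd8a by 2.20 ± 0.25.

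Adjusted over the list alone, these counts were 30 lower for absorptive enterocytes, 33 higher for G2 and M, 30 higher for S phase, 16 higher and 2 lower for active stem cells, 33 higher for ribosome biogenesis and 20 lower for T cells. Median log2 differences and camera's adjusted p were -3.26 (2.17e-18), 1.24 (1.58e-12), 1.35 (7.69e-14), 1.45 (7.03e-07), 1.02 (1.9e-14) and -1.61 (5.22e-07) in that order. Each call was lost with an estimated correlation, at adjusted p = 0.281, 0.352, 0.282, 0.281, 0.281 and 0.352 in turn. The largest changes outside the lists were a rise of the protocadherin Pcdh8 by 2.22 ± 0.25 and of Myc by 2.06 ± 0.23, and the amino acid transporter gene Slc7a15 at -4.87 ± 0.30. Limma called 16287 of 28090 genes, 6590 higher and 9697 lower in Sublow cells. The higher calls were 40.5% of these, and 51.1% when the sample channel alone was used. In 25.4% of genes the 7 values of one gate did not overlap those of the other, where chance gives 0.0583%. Replicates 1 to 3 alone gave 9553 calls, and 4 to 7, where gate equals slide, 15485. Of the marker panel, Sox9 (1.41), Ascl2 (1.73), Smoc2 (1.72), Bmi1 (0.41), Lrig1 (1.35), Mki67 (1.40), Ccnb1 (1.14), Lyz1 (1.00) and Igf1r (1.33) rose and Muc2 (-1.59), Alpi (-2.32), Fabp1 (-3.87), Cdkn1a (-1.22) and Mdm2 (-0.99) fell, while Hopx, Dclk1 and Chga did not pass. The Lyz1 call was lost without replicate 7 (adjusted p = 0.072).

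Low cells differed from Sublow cells by higher secretory and stem cell transcripts and lower goblet transcripts (n = 7 each). Of 30 enteroendocrine genes 28 rose and none fell, with the peptide hormone precursors Nts (neurotensin) at 4.02 ± 0.65 and Tac1 at 3.01 ± 0.52 and the granule protein Scg2 at 3.04 ± 0.53. Of 20 tuft cell genes 13 rose, among them Rgs13 at 3.21 ± 0.58 and Dclk1 at 2.05 ± 0.46. Of 19 active stem cell genes 12 rose and 1 fell, with Lgr5 at 1.31 ± 0.31 and Axin2 at 0.82 ± 0.14, and of 20 Wnt targets 11 rose, with the secreted Wnt inhibitor Wif1 at 1.91 ± 0.35. Of 19 goblet cell genes 9 fell, with Clca1 at -2.86 ± 0.39, Zg16 at -2.35 ± 0.26 and the mucin Muc2 at -1.31 ± 0.23. Of 31 oxidative phosphorylation genes 15 fell, with Sdhd at -0.66 ± 0.12. Of 15 Paneth cell genes 5 rose, among them lysozyme (Lyz1) at 1.15 ± 0.33, whose call was lost without replicate 2 (adjusted p = 0.0645). Proliferation markers were close between the gates, with Mki67 at -0.09 (adjusted p = 0.862) and Ccnb1 at -0.25 (adjusted p = 0.574).

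Adjusted over the list alone, the calls were 29 higher of the enteroendocrine genes, 16 of tuft, 14 of active stem cell (1 lower), 14 of Wnt, 11 of Paneth, and 13 lower of goblet (1 higher) and 22 lower of oxidative phosphorylation. The medians and camera's adjusted p were 2.06 (1.97e-24), 1.45 (3.34e-11), 0.64 (5.85e-07), 0.59 (9.25e-08), 0.77 (0.000225), -0.51 (8.55e-10) and -0.26 (3.34e-11) in that order. With an estimated correlation the adjusted p values were 0.104, 0.105, 0.148, 0.0709, 0.437, 0.105 and 0.0709, so each call was lost. Beyond the lists, the filament protein Vim rose by 2.94 ± 0.39 and the calcium and membrane binding proteins Anxa3 and Ahnak fell by 1.62 and 1.51. Limma called 4555 of 28090 genes, 2671 higher and 1884 lower in Low cells. Slide as a random block lowered this count by more than 1.5 times. The higher share of 58.6% became 81.4% after scale normalisation between arrays. Replicates 1 to 3 alone gave 12 calls, and 4 to 7, where gate equals slide, 3907. Sublow replicates 2 and 3 and Low 3 matched other gates best. In 3.9% of genes the gates did not overlap. Sox9 (1.00), Ascl2 (0.80), Smoc2 (0.68), Hopx (0.68), Lrig1 (0.46), Chga (2.396) and Igfbp4 (0.70) rose and Alpi (-0.99) and Fabp1 (-0.94) fell, while Olfm4, Bmi1, Cdkn1a, Mdm2 and Igf1r did not pass. Ascl2 lost its call without replicate 1, 2, 4, 6 or 7 (adjusted p = 0.0947, 0.0818, 0.101, 0.0749 and 0.0645), Lrig1 without 1, 2, 4, 5 or 6 (0.0803, 0.108, 0.171, 0.0533 and 0.0509) and Fabp1 without 1, 2 or 6 (0.0635, 0.0913 and 0.0671).

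High cells differed from Low cells by higher enteroendocrine, tuft and lysosomal transcripts and lower proliferation, active stem cell and Paneth transcripts (n = 7 each). All 32 S phase genes and 33 of 34 G2 and M genes fell, with the licensing factor Cdt1 at -1.78 ± 0.17, Bub1 at -1.96 ± 0.22 and Mki67 at -1.45 ± 0.23. Of 19 active stem cell genes 17 fell, with Lgr5 at -2.25 ± 0.31, Tnfrsf19 at -2.001 ± 0.26 and Olfm4 at -1.78 ± 0.29, and 2 rose, among them Igfbp4 by 0.91 ± 0.14. Of 15 Paneth genes 14 fell, with Ang4 at -2.73 ± 0.45 and the alpha-defensin Defa29 at -2.50 ± 0.31. Of 30 enteroendocrine genes 28 rose and 2 fell, with Chgb at 3.15 ± 0.63, the prohormone convertase Pcsk1 at 2.79 ± 0.39 and Chga at 2.45 ± 0.51. Of 20 tuft genes 15 rose, with Il17rb at 2.17 ± 0.25 and Sh2d6 at 2.06 ± 0.28, and of 22 lysosomal genes 20 rose, with the protease Ctsl at 2.37 ± 0.29. Markers of T cells rose too, 14 of 20, with Gzma at 1.52 ± 0.31. The cell cycle inhibitor Cdkn1a rose by 1.94 ± 0.22.

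The medians and camera's adjusted p were -1.31 (4.89e-21) for S phase, -1.49 (5.39e-21) for G2 and M, -1.23 (6.53e-09) for active stem cells, -1.995 (2.37e-08) for Paneth, 1.94 (1.87e-05) for enteroendocrine, 1.37 (0.00305) for tuft, 0.94 (7.48e-09) for lysosomal and 0.58 (0.0228) for T cell genes. Adjusted over the list alone, 32, 33, 17 and 15 fell in the first 4 lists (2 active stem cell genes rose), 28, 15, 20 and 15 rose in the other 4, and 2 enteroendocrine and 1 lysosomal gene fell. With an estimated correlation the calls were lost at adjusted p = 0.141, 0.141, 0.141, 0.239, 0.579, 0.579, 0.141 and 0.676. The T cell call was also lost with the sample channel alone, with scale normalisation and with the stricter filter on dim probes. Genes described as markers of reserve stem cells divided, 5 of 10 higher and 4 lower, and the list was not called (adjusted p = 0.559; its median of 0.27 and the test differed in sign). Hopx rose by 1.15 ± 0.17 and Sp5 fell by 1.87 ± 0.21. Afp, encoding alpha-fetoprotein, had the largest rise at 6.33 ± 0.94, followed by Plet1 at 3.81 ± 0.36 and the monoamine transporter Slc18a2 at 3.60 ± 0.26. Dclk1, at 1.09 ± 0.46, passed narrowly (adjusted p = 0.0498), and its call was lost when replicate 1, 2, 4, 6 or 7 was left out (0.175, 0.0935, 0.0972, 0.0573 and 0.123). Limma called 13474 of 28090 genes, 8501 higher and 4973 lower in High cells. The 63.1% that were higher became 53% with the scanner's own log ratio and 45% with the sample channel alone. Replicates 1 to 3 alone gave 6990 calls, and 4 to 7, where gate equals slide, 12583. In 18.3% of genes the gates did not overlap. Sox9 (1.07), Bmi1 (0.62), Fabp1 (2.24) and Mdm2 (0.98) rose and Ascl2 (-1.66), Smoc2 (-1.23), Lrig1 (-1.04), Ccnb1 (-1.62), Lyz1 (-1.80) and Igf1r (-1.27) fell. Muc2, of which 1 other probe was called in the opposite direction, and Alpi did not pass, although Alpi did with the replicate number as a block (0.0112).

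Set against unsorted epithelium, the mean of the 4 sorted populations was enriched in enteroendocrine transcripts and depleted of enterocyte and lymphocyte transcripts (n = 7 each). All 20 T cell markers fell, with Klrd1 at -3.71 ± 0.27, Gzma at -3.47 ± 0.24 and Cd7 at -2.91 ± 0.17, and 29 of 30 absorptive genes fell, with Slc2a2 at -3.66 ± 0.29 and Cyp3a11 at -3.22 ± 0.28. Of 31 oxidative phosphorylation genes 28 fell, with Uqcrfs1 at -0.77 ± 0.10. These 3 lists had medians of -2.16 (camera's adjusted p = 2.42e-26), -2.02 (4.55e-29) and -0.39 (9.67e-13), the identical counts adjusted over the list alone (20, 29 and 28), and calls that held with an estimated correlation (adjusted p = 0.0258 each). Of 30 enteroendocrine genes 29 rose, and 30 adjusted over the list alone, with Chgb at 3.16 ± 0.50 and Cpe at 3.02 ± 0.43 (median 2.09, adjusted p = 1.11e-16, and adjusted p = 0.156 with an estimated correlation). Limma called 10895 of 28090 genes, 5683 higher and 5212 lower in sorted cells. An equal mean of the 4 gates is not the mixture of cells in the tissue. Markers of red blood cells were lower in sorted cells as well, by a median of 1.41 (adjusted p = 0.000159; adjusted p = 0.156 with an estimated correlation). Of the marker panel, Sox9 (1.47), Lgr5 (0.97), Ascl2 (0.62), Olfm4 (0.68), Smoc2 (0.78), Bmi1 (0.49), Hopx (0.88), Dclk1 (1.24), Chga (2.404), Lyz1 (0.65), Igf1r (0.59) and Igfbp4 (0.48) rose and Alpi (-1.73) and Fabp1 (-2.89) fell, while Lrig1, Mki67, Ccnb1, Muc2, Cdkn1a and Mdm2 did not pass. Ascl2 lost its call without replicate 7 (adjusted p = 0.0589), Olfm4 without 1 (0.0542) and Lyz1 without 2, 4, 5, 6 or 7 (0.0722, 0.0967, 0.0947, 0.148 and 0.11).

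Irradiation effects were taken in vehicle mice at 5 days, from 3 irradiated and 3 non-irradiated animals per population. A first comparison averaged the 4 populations of each mouse. Regenerative epithelium genes rose, 18 of 30 with 2 falling. Anxa1 rose by 6.26 ± 0.24, Msln (mesothelin) by 4.44 ± 0.31, Ly6d by 3.87 ± 0.26 and the alarmin Il33 by 3.84 ± 0.18, and outside the list Anxa10 rose by 6.30 ± 0.32. Glutathione and NRF2 targets rose, 15 of 22 with 1 falling, with the carbonyl reductase Cbr3 at 3.41 ± 0.34 and the glutathione transferase Gsta2 at 3.40 ± 0.45. Tuft genes fell, 16 of 20, with Rgs13 at -4.64 ± 0.31 and Dclk1 at -2.34 ± 0.23. Paneth genes fell, 11 of 15, with Ang4 at -2.65 ± 0.44. Markers of T cells fell, 17 of 20 with 1 rising, with Gzma at -2.57 ± 0.38. The goblet mucin Muc2 fell by 0.94 ± 0.11.

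For the mouse means the medians and camera's adjusted p were 1.27 (3.59e-11), 0.90 (3.51e-09), -1.51 (1.71e-09), -2.16 (0.000298) and -0.87 (2.77e-06), with 19, 16, 16, 11 and 17 genes moving in the named direction when adjusted over the list alone. Each call was lost with an estimated correlation, at adjusted p = 0.23, 0.23, 0.251, 0.67 and 0.67. Limma called 8548 of 26889 genes, 3516 higher and 5032 lower after irradiation, and 49.3% of genes did not overlap between the groups where chance gives 10%. The 41.1% that were higher became 53.3% with the sample channel alone. The count fell to 3517, 4191 or 5468 without replicate 1, 2 or 3 of every group, and to 5030 without irradiated vehicle replicate 2. Of the marker panel, Bmi1 (0.62) rose and Sox9 (-0.42), Lgr5 (-1.01), Olfm4 (-2.01), Smoc2 (-0.46), Hopx (-0.60), Chga (-2.75), Lyz1 (-2.22) and Igf1r (-1.25) fell, while Ascl2, Lrig1, Mki67, Ccnb1, Alpi, Fabp1, Cdkn1a, Mdm2 and Igfbp4 did not pass. With the replicate number as a block Mki67 (0.0449) and Ccnb1 (0.0131) did. Without irradiated replicate 2 the calls of Sox9, Lgr5, Smoc2, Hopx and Chga were lost (adjusted p = 0.0622, 0.0516, 0.0801, 0.0534 and 0.0583). Non-irradiated replicate 3 decided Sox9 (0.0574), Hopx (0.102) and Chga (0.0553), non-irradiated replicate 2 Lgr5 (0.0617), Smoc2 (0.091) and Hopx (0.0985), irradiated replicate 1 Chga (0.0505), and irradiated replicate 3 and non-irradiated replicate 1 Smoc2 (0.0609 and 0.0505). Bmi1 and Lyz1 lost theirs without replicate 2 of every group (0.0503 and 0.105) and Igf1r without replicate 1 (0.0843).

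High cells of irradiated mice carried more proliferation and growth transcripts and fewer tuft and enteroendocrine transcripts (n = 3 each). Of 34 G2 and M genes 31 rose, with Mybl2 at 2.10 ± 0.31 and Cdc20 at 2.01 ± 0.44, and of 31 S phase genes 27 rose, with the ribonucleotide reductase subunit Rrm2 at 2.88 ± 0.50 and Ccne1 at 2.10 ± 0.34. Of 33 ribosome biogenesis genes 28 rose, with Nhp2 at 1.68 ± 0.29. Of 20 tuft genes 17 fell, and the losses were deep, with Rgs13 at -7.21 ± 0.66, Alox5 at -5.67 ± 0.56 and Dclk1 at -4.20 ± 0.52. Of 30 enteroendocrine genes 7 fell and 1 rose, with Nts at -4.79 ± 1.31 and Sst at -2.22 ± 0.51. Of 30 regenerative genes 13 rose and 2 fell, with Anxa1 at 6.71 ± 0.48, Msln at 4.27 ± 0.52 and Ly6d at 3.83 ± 0.49. Of 19 active stem cell genes 4 rose and none fell, among them Lrig1 at 1.09 ± 0.30, Smoc2 at 1.15 ± 0.36 and the Wnt-responsive factor Sp5 at 1.81 ± 0.50. Lgr5 was at 1.43 ± 0.72 and did not pass (adjusted p = 0.149; with slide as a block 0.036). Spib, a transcription factor that tuft and lymphoid cells express, fell by 6.03 ± 0.45, and Afp was at -7.77 ± 1.52. Markers of T cells fell, 12 of 20 with Cd2 rising by 1.93 ± 0.37, and Gzma fell by 3.198 ± 0.55.

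In irradiated High cells the medians and camera's adjusted p were 1.65 (4.77e-19) for G2 and M, 1.41 (1.66e-16) for S phase, 1.23 (1.05e-17) for ribosome biogenesis, -3.57 (3e-19) for tuft, -1.54 (0.000684) for enteroendocrine, 1.20 (1.49e-08) for regenerative, 0.82 (0.00092) for active stem cell and -0.99 (0.000741) for T cell genes. Of these, 32, 28, 29, 17, 11, 15, 7 and 14 genes moved in the named direction when adjusted over the list alone. No call held with an estimated correlation, at adjusted p = 0.278, 0.278, 0.278, 0.106, 0.647, 0.121, 0.603 and 0.603, and fry lost the active stem cell (0.0639) and enteroendocrine (0.0582) calls. The 3 slides, each holding all treatments of 1 replicate number, gave medians of 1.21, 1.70 and 2.16 for G2 and M and -4.15, -3.11 and -3.45 for tuft genes. Without replicate 3 of every group the T cell call was lost (adjusted p = 0.0804). Targets of p53 divided, 8 of 30 higher and 6 lower (8 and 7 adjusted over the list alone), with Phlda3 at 3.27 ± 0.25, Pvt1 at 2.90 ± 0.26 and Cdkn1a at -1.43 ± 0.44. Their test leaned upward (adjusted p = 0.0459) against a median of -0.19 and was lost with slide as a block (0.0951), with scale normalisation, with the stricter filter on dim probes, without replicate 2 or 3 (0.0589 and 0.177) and with an estimated correlation (adjusted p = 0.304). Limma called 6798 of 26932 genes, 2603 higher and 4195 lower, and 9455 with slide as a block. The 38.3% that were higher became 49.9% with the scanner's log ratio and 55.8% with the sample channel alone. The count fell to 3811 or 4031 without irradiated High replicate 1 or 2, to 3862 without non-irradiated High replicate 3, and to 1938 without replicate 2 of every group. Without that non-irradiated replicate 3 the calls of Smoc2, Sp5 and Cdkn1a were lost, at adjusted p = 0.149, 0.0787 and 0.109. Irradiated replicates 1 and 2 also decided the calls of Smoc2 (0.0792 and 0.0609 without them) and Cdkn1a (0.1 and 0.0688). Without replicate 1 or 2 of every group Nts (0.156 and 0.0748) and Lrig1 (0.0954 and 0.0734) lost theirs, and without replicate 2 so did Cdc20 (0.0594) and Sst (0.0796). In 40.3% of genes the groups did not overlap, where chance gives 10%. Mki67 (1.45) and Ccnb1 (1.96) rose and Sox9 (-0.76) and Hopx (-1.45) fell. Sox9 lost its call without irradiated replicate 1 or 2 or non-irradiated replicate 1 or 3 (0.166, 0.161, 0.0526 and 0.173), Mki67 without irradiated 1 or 2 or non-irradiated 2 or 3 (0.119, 0.0822, 0.0603 and 0.266) and Ccnb1 without non-irradiated 3 (0.102). Ascl2, Chga, Lyz1 and Mdm2 passed with slide as a block alone (0.0237, 0.00272, 0.03 and 0.00831), and Olfm4, Bmi1, Muc2, Alpi, Fabp1, Igf1r and Igfbp4 did not pass.

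**Figure D2:**
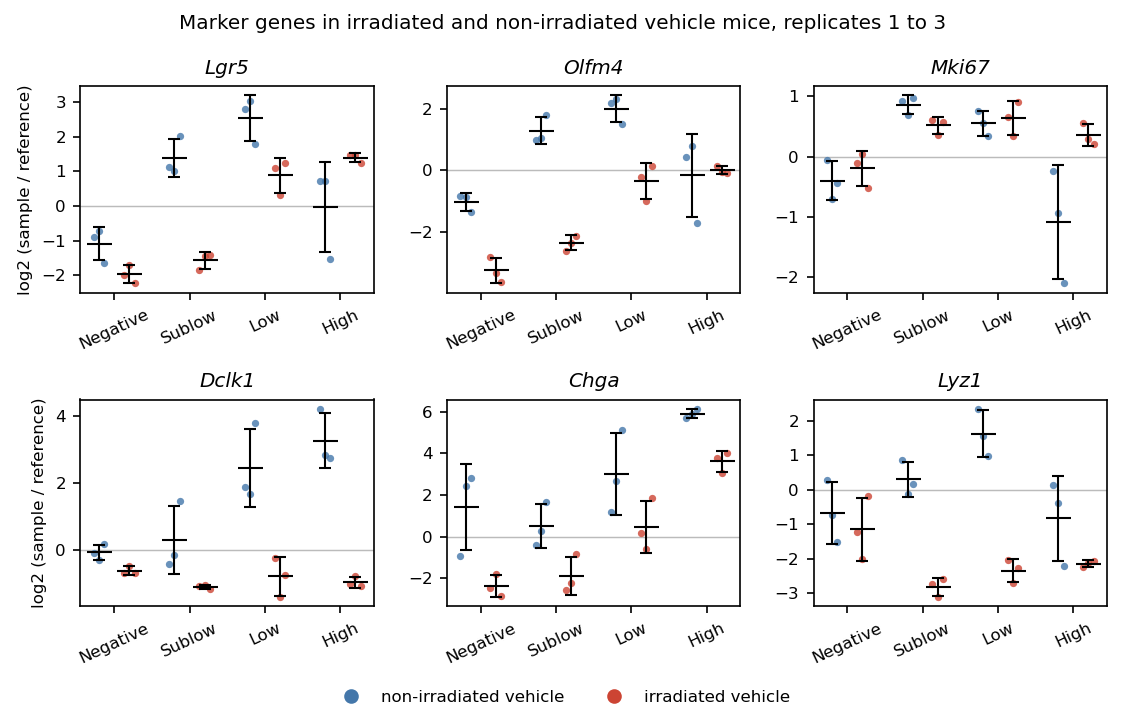
Log2 ratio of sample to reference (vertical axis) for 6 marker genes in the 4 Sox9-EGFP gates (horizontal axis) of non-irradiated (blue) and irradiated (red) vehicle mice, with 1 point per mouse (n = 3) and bars for mean and SD. Dclk1 fell by 4.20 in High cells and by 3.23 in Low cells, and Lyz1 fell by 3.96 in Low cells.

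Low cells of irradiated mice lost Paneth, tuft and enteroendocrine transcripts and gained regenerative, detoxification and cholesterol synthesis transcripts (n = 3 each). Of 15 Paneth genes 12 fell, with Defa29 at -5.16 ± 0.77, Ang4 at -4.82 ± 0.72 and Lyz1 at -3.96 ± 0.65, and of 20 tuft genes 15 fell, with Rgs13 at -4.92 ± 0.66 and Dclk1 at -3.23 ± 0.52. Of 30 enteroendocrine genes 14 fell, with Nts at -5.87 ± 1.31. Of 30 regenerative genes 15 rose and 1 fell, with Anxa1 at 5.75 ± 0.48 and Il33 at 4.48 ± 0.48, while Ccn1, a target of YAP, fell by 2.54 ± 0.46. Of 22 NRF2 targets 14 rose, with Gsta2 at 3.66 ± 0.62 and Cbr3 at 2.85 ± 0.47. Of 24 cholesterol synthesis genes 13 rose, with Idi1 at 1.25 ± 0.26. Of 30 p53 targets 9 rose, with Phlda3 at 1.94 ± 0.25 and Zmat3 at 1.38 ± 0.26. Active stem cell genes fell in 4 of 19 cases, including Olfm4 by 2.36 ± 0.67, Rgmb by 1.51 ± 0.32 and the Wnt regulator Rnf43 by 1.22 ± 0.30. Lgr5 was at -1.64 ± 0.72 (adjusted p = 0.137; with slide as a block 0.0246). The IGF1 receptor gene Igf1r fell by 1.45 ± 0.40. Mki67 was at 0.08 (adjusted p = 0.95).

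Irradiated vehicle Low replicates 1 and 2 matched the Sublow profile best (correlation 0.291 and 0.349, against -0.009 and 0.068 with the Low profile), and a mix of cells was not tested in this gate. In irradiated Low cells the medians and camera's adjusted p were -3.94 (1.21e-15) for Paneth, -2.01 (9.81e-16) for tuft, -1.87 (5.21e-11) for enteroendocrine, 1.42 (8.51e-13) for regenerative, 1.17 (9.19e-14) for NRF2, 0.76 (3.46e-10) for cholesterol, 0.33 (0.00472) for p53 and -0.52 (0.00101) for active stem cell genes. The genes moving in the named direction, adjusted over the list alone, were 13, 17, 21, 19, 15, 16, 11 and 4. The regenerative and NRF2 calls held with an estimated correlation (adjusted p = 0.0178 each), and the others were lost at adjusted p = 0.0898, 0.0789, 0.476, 0.0898 (cholesterol), 0.0898 (p53) and 0.49 (active stem cell). The 3 slides gave medians of -4.29, -4.27 and -3.14 for Paneth and 1.17, 1.43 and 1.18 for regenerative genes. The active stem cell call was lost with fry (0.0565) and without replicate 2 of every group, where the median was -0.38, and without Low irradiated vehicle replicate 2 the calls of Olfm4, Rnf43 and Igf1r were lost (adjusted p = 0.102, 0.0525 and 0.128). Olfm4 also lost its call without non-irradiated Low replicate 2 (0.0595) and Igf1r without non-irradiated Low replicate 1 (0.0627). Without replicate 1 or 2 of every group Nts lost its call (0.0596 and 0.0598), and without replicate 2 so did Rgmb (0.16). Limma called 3392 of 26932 genes, 1708 higher and 1684 lower, and 5969 with slide as a block. The count fell to 1657 without irradiated Low replicate 2, to 2008 without non-irradiated Low replicate 3, and to 1337 or 758 without replicate 1 or 2 of every group. In 28.9% of genes the groups did not overlap. Bmi1 rose by 0.61, a call lost without irradiated replicate 1 or 2 or non-irradiated replicate 1 or 2 (adjusted p = 0.132, 0.081, 0.118 and 0.111). Sox9, Hopx and Chga passed with slide as a block alone (0.00756, 0.00364 and 0.00222), and Ascl2, Smoc2, Lrig1, Ccnb1, Muc2, Alpi, Fabp1, Cdkn1a, Mdm2 and Igfbp4 did not pass.

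Sublow cells of irradiated mice gained regenerative, NRF2 and glycolytic transcripts and lost Paneth and active stem cell transcripts (n = 3 each). Of 30 regenerative genes 17 rose and 1, Ccn1, fell, with Anxa1 at 5.81 ± 0.48, Msln at 4.35 ± 0.52 and Il33 at 4.14 ± 0.48, and Anxa10 rose by 6.77 ± 0.56. Of 22 NRF2 targets 15 rose, with Gsta2 at 4.08 ± 0.62, Gsta1 at 3.84 ± 0.59 and Cbr3 at 3.62 ± 0.47. Of 18 glycolytic genes 8 rose, with Gapdh at 1.33 ± 0.23 and the lactate exporter Slc16a3 at 1.61 ± 0.42. Of 30 p53 targets 7 rose and 1 fell, with Plk2 at 2.31 ± 0.40 and Phlda3 at 2.23 ± 0.25 and Sesn1 at -1.11 ± 0.32. Of 15 Paneth genes 11 fell, with Defa29 at -4.28 ± 0.77 and Ang4 at -4.09 ± 0.72. Of 19 active stem cell genes 10 fell, with Olfm4 at -3.63 ± 0.67, Lgr5 at -2.96 ± 0.72, and Smoc2 at -1.51 ± 0.36. Igf1r fell by 2.15 ± 0.40. Mki67 was at -0.35 (adjusted p = 0.821).

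In irradiated Sublow cells the medians and camera's adjusted p were 1.48 (4.37e-21) for regenerative, 1.14 (4.75e-16) for NRF2, 0.68 (7.89e-08) for glycolytic, 0.27 (4.99e-05) for p53, -3.105 (1.01e-12) for Paneth and -1.03 (3.05e-06) for active stem cell genes. In the named direction moved 19, 15, 10, 10, 11 and 10 genes, adjusted over the list alone. With an estimated correlation the regenerative, NRF2 and p53 calls held (adjusted p = 0.00138, 0.00443 and 0.0124), and the glycolytic, Paneth and active stem cell calls were lost (adjusted p = 0.138, 0.147 and 0.348). The 3 slides gave medians of 1.36, 1.36 and 1.82 for regenerative and -0.73, -0.97 and -1.19 for active stem cell genes. Limma called 2286 of 26932 genes, 1101 higher and 1185 lower, and 4014 with slide as a block. The count fell to 1357 without irradiated Sublow replicate 2, to 1423 without non-irradiated Sublow replicate 3, and to 602, 1002 or 1404 without replicate 1, 2 or 3 of every group. The call of Slc16a3 was lost without that non-irradiated replicate 3 (adjusted p = 0.0579) and without replicate 1 or 2 of every group (0.17 and 0.116). Those 2 exclusions also removed the calls of Lgr5 (0.102 and 0.109) and Smoc2 (0.0772 and 0.145). In 31.8% of genes the groups did not overlap. Lyz1 fell by 3.105 and lost its call without replicate 2 of every group (0.0816). Bmi1 rose by 0.64, a call lost without any 1 of irradiated replicates 1 to 3 (0.151, 0.0699 and 0.0711) or non-irradiated replicates 1 to 3 (0.0995, 0.106 and 0.0659). Dclk1, Chga and Muc2 passed with slide as a block alone (0.0181, 0.00469 and 0.0451), and Sox9, Ascl2, Hopx, Lrig1, Ccnb1, Alpi, Fabp1, Cdkn1a, Mdm2 and Igfbp4 did not pass.

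Negative cells of irradiated mice showed the regenerative, NRF2 and p53 changes together with lower enteroendocrine, lymphocyte and red blood cell transcripts (n = 3 each). Of 30 regenerative genes 18 rose and 1 fell, with Anxa1 at 6.79 ± 0.48, Msln at 5.21 ± 0.52 and the growth factor Ereg (epiregulin) at 3.89 ± 0.48, and Anxa10 rose by 7.58 ± 0.56. Vsig1 and Fn1 (fibronectin) were not well above background before irradiation and rose at least 41.2-fold and at least 20.1-fold. Of 22 NRF2 targets 11 rose and 1 fell, with Cbr3 at 4.02 ± 0.47. Of 30 p53 targets 12 rose and 3 fell, with Phlda3 at 3.78 ± 0.25 and Sesn1 at -1.89 ± 0.32. Of 30 enteroendocrine genes 21 fell, with Nts at -5.70 ± 1.31 and Chga at -3.79 ± 0.94, and Muc2 fell by 2.48 ± 0.41, while the goblet list was not called (7 of 18 lower, adjusted p = 0.187). Of 20 T cell markers 18 fell, with Gzma at -3.90 ± 0.55 and Klrd1 at -3.63 ± 0.64. Of 6 red blood cell genes 5 fell, with Hbb-bt at -2.31 ± 0.50. Of 16 myeloid markers 8 rose and 3 fell, with Cx3cr1 at 2.42 ± 0.26, S100a9 at least 9.15-fold and Il1b at least 5.54-fold higher, and Itgam at -3.07 ± 0.38. The polycomb gene Bmi1 rose by 1.19 ± 0.20.

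In irradiated Negative cells the medians and camera's adjusted p were 1.54 (1.15e-11) for regenerative, 0.98 (1.25e-05) for NRF2, 0.36 (0.000568) for p53, -2.10 (1.25e-05) for enteroendocrine, -1.89 (4.6e-09) for T cell, -2.05 (0.015) for red blood cell and 0.44 (0.0056) for myeloid genes. In that order 21, 12, 13, 24, 19, 5 and 8 genes moved in the named direction, adjusted over the list alone. The regenerative call held with an estimated correlation (adjusted p = 0.0443), and the others were lost at adjusted p = 0.317, 0.0529, 0.781, 0.596, 0.753 and 0.596. The 3 slides gave medians of 1.64, 1.46 and 1.63 for regenerative, -0.91, -1.93 and -3.95 for enteroendocrine and -1.71, -2.28 and -1.73 for T cell genes. Without replicate 3 of every group the red blood cell and myeloid calls were lost (adjusted p = 0.0672 and 0.0852), and without replicate 2 the red blood cell call (0.0637) and that of Chga (0.11). Limma called 8225 of 26932 genes, 3063 higher and 5162 lower. The 37.2% that were higher became 50.6% with the sample channel alone. The count fell to 5215 without non-irradiated Negative replicate 2 and to 3344 without replicate 2 of every group. In 46.1% of genes the groups did not overlap. Olfm4 (-2.23), Smoc2 (-0.94) and Igf1r (-1.17) fell. The Smoc2 call was lost without any 1 of irradiated replicates 1 to 3 (0.0745, 0.0688 and 0.152) or non-irradiated replicates 1 to 3 (0.0758, 0.12 and 0.093), that of Igf1r without irradiated 1 or 2 or non-irradiated 1 or 3 (0.0669, 0.0909, 0.062 and 0.123), and that of Olfm4 without replicate 1 or 2 of every group (0.0634 and 0.157). Sox9, Lgr5, Ascl2, Hopx, Lrig1, Dclk1, Mki67, Ccnb1, Lyz1, Alpi, Fabp1, Cdkn1a, Mdm2 and Igfbp4 did not pass.

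**Figure D3:**
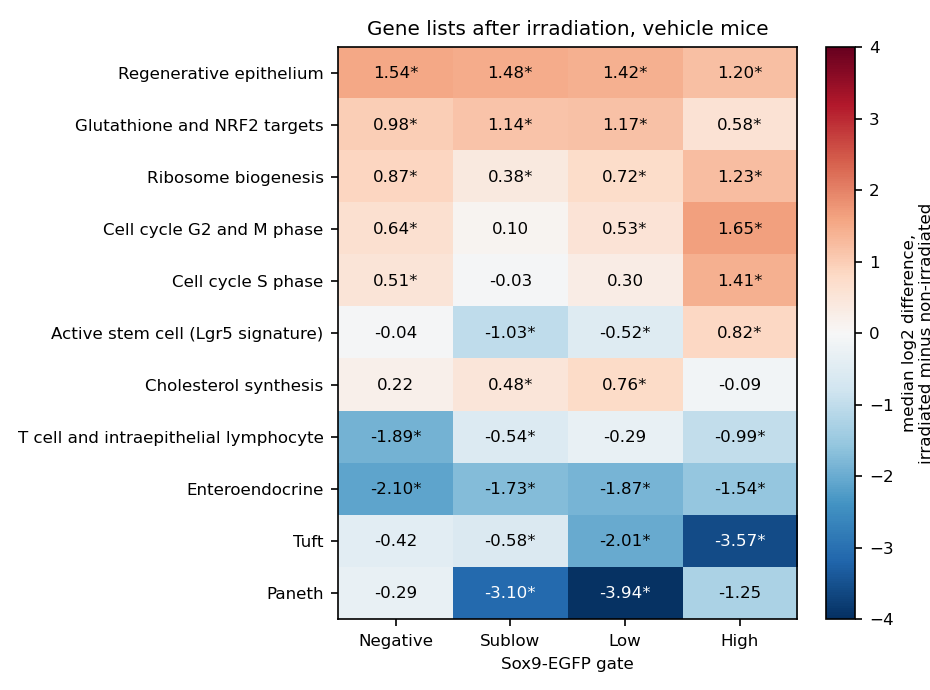
Median log2 difference, irradiated minus non-irradiated vehicle mice (colour and printed value, n = 3 per group), of 11 gene lists (vertical axis) in the 4 Sox9-EGFP gates (horizontal axis), with an asterisk where camera's adjusted p with the preset correlation passed. The regenerative list is higher in all 4 gates (1.54, 1.48, 1.42 and 1.20 from Negative to High), while the active stem cell list is at 0.82 in High and at -1.03 in Sublow cells.

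The irradiation effect in High cells was tested directly against that in Low cells. Fry called the active stem cell, cholesterol and glycolytic lists alone among the 6 given here. The difference of the effects had a median of 1.16 for G2 and M (camera's adjusted p = 2.85e-16), 1.17 for S phase (3.97e-17) and 1.43 for active stem cell genes (4.67e-16), and of 2.65 for Paneth genes (1.07e-13), which fell further in Low cells. It was -0.89 for glycolytic (1.09e-09) and -0.72 for cholesterol synthesis genes (5.06e-10). Scale normalisation lowered the cell cycle medians to 0.196 for G2 and M and 0.178 for S phase, where S phase was not called (0.135). These calls were lost with an estimated correlation, at adjusted p = 0.242, 0.207, 0.0792, 0.101, 0.0941 and 0.101, although the active stem cell call held with slide as a block (0.0424). Adjusted over the list alone, 0 of 34 G2 and M and 0 of 31 S phase genes passed, 16 of 19 active stem cell and 12 of 15 Paneth genes had the more positive effect in High cells, and 11 of 18 glycolytic and 11 of 24 cholesterol genes the more positive one in Low cells. Limma called 26 single genes, 4 with the more positive effect in High cells, among them the amino acid transporter Slc38a5 at 2.69 ± 0.38 and the Notch ligand Dll3 at 2.401 ± 0.43, and 22 with the more positive effect in Low cells, among them Pax1 at -2.31 ± 0.33, Igfbp2 at -2.19 ± 0.30 and Slc13a3 at -2.13 ± 0.27. The count was 496 with slide as a block, of which 207 had the more positive effect in High and 289 in Low cells, 1 and 0 without replicate 1 and 2 of every group, 954 without replicate 3 and 360 without non-irradiated Low replicate 3. It lay between 7 and 14 without any 1 of High irradiated replicates 1 and 3, High non-irradiated replicate 2, Low irradiated replicate 1 and Low non-irradiated replicates 1 and 2. No panel gene passed, and with slide as a block Lgr5 (3.07 ± 1.02, 0.0326), Ascl2 (2.01, 0.041), Smoc2 (1.68, 0.0284) and Lyz1 (2.65, 0.0365) did. Dll3 lost its call without Low irradiated or non-irradiated replicate 1 (adjusted p = 0.0655 and 0.0536).

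With IGF1 and no irradiation, limma called 3, 4, 0 and 0 genes in Negative, High, Low and Sublow cells (n = 3 each). The counts depend on the fit: array weights gave 2193, 626, 16 and 5. In Negative cells 3 genes passed. Angptl4, a secreted inhibitor of lipoprotein lipase that fasting induces, fell by 2.56 ± 0.34 (adjusted p = 0.000279), the clock output gene Dbp rose by 3.07 ± 0.52 (adjusted p = 0.0092), and the core clock gene Arntl fell by 1.33 ± 0.22 (adjusted p = 0.00718). Angptl4 was also lower in Sublow (-0.94), Low (-0.70) and High cells (-1.14), each ± 0.34. It did not pass there, nor with slide as a block (adjusted p = 0.497, 0.69 and 0.0893). In High cells 4 genes passed, all higher, including Ankrd34c at 1.02 ± 0.18, Tmem211 at 0.72 ± 0.13 and Apcs at 0.49 ± 0.09. At an unadjusted p below 0.05 limma listed 1308, 894, 767 and 787 genes in Negative, High, Low and Sublow cells. All such counts here and below are fewer than chance gives. Groups did not overlap in 7.2%, 11.7%, 8.4% and 11% of genes where chance gives 10%. No panel gene passed in any population. With slide as a block 30, 29, 0 and 1 genes passed, with Sox9 in Negative cells at -0.92 ± 0.27 (0.0447, against 0.65 without).

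The single-gene calls with IGF1 rested on few animals. Without Negative vehicle replicate 2 the count rose to 747. It was 39 or 17 without Negative IGF1 replicate 1 or 3, 121 without replicate 2 of every group and 1 without replicate 3. In High cells it ranged from 0, without vehicle replicate 2 or 3, to 20 without replicate 3 of every group, and was 14, 1 and 7 without IGF1 replicates 1, 2 and 3 and 7 without vehicle replicate 1. Dbp lost its call without IGF1 replicate 2 or vehicle replicate 1 or 3 (adjusted p = 0.0848, 0.106 and 0.0516) and Arntl without vehicle replicate 1 (0.0746). Angptl4 lost its call without replicate 1 of every group (-2.38, adjusted p = 0.562), and no single library removed it. Without vehicle replicate 2 Ankrd34c, Tmem211 and Apcs lost theirs (0.294, 0.137 and 0.14), as they did without vehicle replicate 3 (0.114, 0.114 and 0.17). Tmem211 and Apcs also depended on vehicle replicate 1 (0.111 and 0.111), IGF1 replicate 1 (0.0722 and 0.205) and IGF1 replicate 2 (0.138 and 0.202), and Ankrd34c on IGF1 replicate 3 (0.261). In Low cells 7 or 4 genes were called without vehicle replicate 1 or 2, and 5 without replicate 3 of every group.

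**Figure D4:**
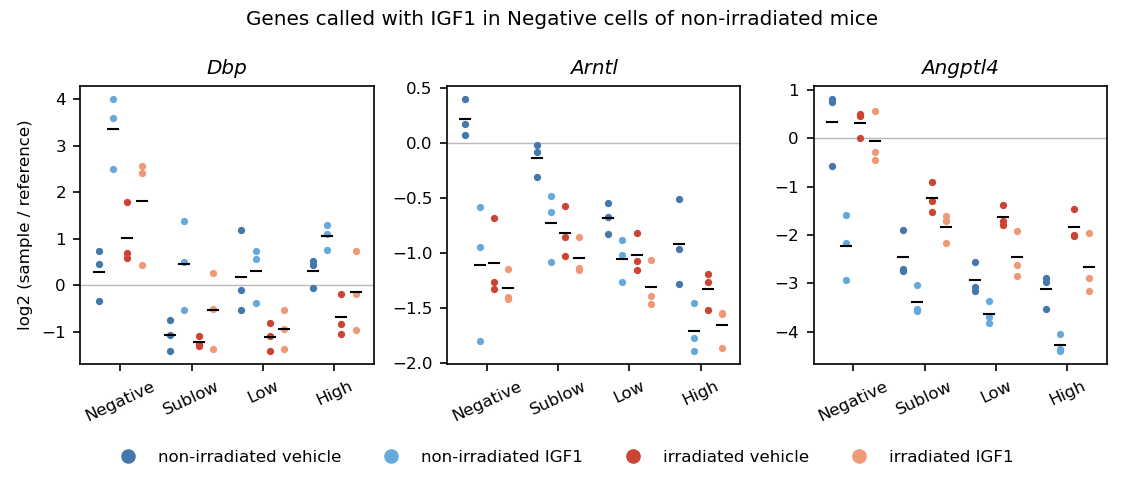
Log2 ratio of sample to reference (vertical axis) for Dbp, Arntl and Angptl4 in the 4 Sox9-EGFP gates (horizontal axis) under 4 treatments (colours), with 1 point per mouse (n = 3) and a line at the mean. Without irradiation, Angptl4 fell by 2.56 and Dbp rose by 3.07 with IGF1 in Negative cells.

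Camera with its preset correlation called gene lists with IGF1 in non-irradiated mice, which neither fry nor an estimated correlation did. Heat shock genes (15 measured) had medians of -0.50 in Negative, -0.63 in Sublow, -0.46 in Low and -0.45 in High cells, at camera's adjusted p = 3.75e-11, 7.51e-12, 1.67e-08 and 6.92e-12. Adjusted over the list alone, 3, 10, 0 and 5 of them fell. Cholesterol synthesis genes had medians of 0.36 in Sublow (8.12e-10) and 0.32 in Low cells (2.41e-09). Tuft genes were at -0.84 in Low cells (1.14e-15), enteroendocrine genes at -1.77 in Negative cells (1.31e-24, 14 of 30 lower adjusted over the list alone), goblet genes at 0.52 in Sublow cells (1.56e-07), and G2 and M genes at -0.44 in High cells (1.12e-08). Active stem cell genes were at -0.26 in Low cells (0.00546), where scale normalisation turned the median to 0.45 (adjusted p = 0.286), and were not called in High cells (0.257). The heat shock adjusted p with an estimated correlation was 0.0986, 0.0669, 0.157 and 0.066, that of cholesterol genes 0.251 and 0.195, and those of tuft, enteroendocrine, goblet, G2 and M and active stem cell genes 0.157, 0.215, 0.278, 0.953 and 0.783. Over the mouse means limma called 0 genes (998 at an unadjusted p below 0.05; 0 with the replicate number as a block), and 9 without vehicle replicate 1. Heat shock genes had a median of -0.55 (adjusted p = 8.93e-14) and tuft genes of -0.51 (4.53e-15) there, each with adjusted p = 0.0826 with an estimated correlation.

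In irradiated mice limma called 4 genes with IGF1 in Negative cells (n = 3 each), and 1325 there and 3 in Sublow cells with array weights. Of 10 splits of the 6 Negative samples 4 called at least 4 genes, with up to 1236, and 10 are too few to decide. Myo15, an unconventional myosin, fell by 0.94 ± 0.13 (adjusted p = 0.000537) and the metal ion transporter Slc11a1 of phagocytes by 0.66 ± 0.12 (0.0419) in Negative cells. Limma called 0 genes in Sublow, Low and High cells, with 261, 517 and 562 at an unadjusted p below 0.05 beside 822 in Negative cells, and groups did not overlap in 6.6%, 6.5%, 4.4% and 6.3% of genes. With slide as a block the Negative count was 13. It was 53 without IGF1 replicate 2, 7 without vehicle replicate 1, 1 without IGF1 replicate 1 or vehicle replicate 2 or 3, 30 without replicate 2 of every group and 0 without replicate 3. In High cells 3 genes were called without replicate 3 of every group. Slc11a1 lost its call without any 1 of the 3 vehicle replicates (adjusted p = 0.0763, 0.113 and 0.246) or IGF1 replicate 1 or 3 (0.843 and 0.318), and Myo15 without replicate 1 or 3 of every group (0.684 and 0.714). Growth-related lists were lower in High cells, with medians of -0.45 for G2 and M (camera's adjusted p = 7.02e-10), -0.35 for S phase (5.17e-07) and -0.37 for ribosome biogenesis genes (1.98e-12), each lost with fry and with an estimated correlation (0.75). In Negative cells interferon response genes were at 0.54 (1.84e-11), with Ifit1 at 1.56 ± 0.64, and myeloid genes at -0.47 (9.27e-08), with Cx3cr1 at -1.03 ± 0.26. Adjusted over the list alone, 4 interferon genes rose and 3 myeloid genes fell. In Low cells active stem cell genes were at 0.20 (0.00267), which scale normalisation turned to -0.58 (adjusted p = 0.404), and enteroendocrine genes at 0.49 (0.000593). With an estimated correlation the adjusted p was 0.165 and 0.119 in Negative cells and 0.82 for both in Low cells, and fry called none of these lists. No panel gene passed in any gate.

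Whether the IGF1 effect differed between irradiated and non-irradiated mice was tested in each gate. Limma called 0 genes in High, Low, Sublow and Negative cells, with 349, 991, 424 and 601 at an unadjusted p below 0.05 and 0, 0, 0 and 2 with slide as a block. Leaving out Negative irradiated IGF1 replicate 2 gave 26 and Negative non-irradiated vehicle replicate 2 gave 20. No gene separated the IGF1 effect in High cells from that in Low cells (847 at an unadjusted p below 0.05). In irradiated mice averaged over the gates limma also called 0 genes (452 at an unadjusted p below 0.05; 0 with the replicate number as a block), and heat shock genes were at -0.16 (camera's adjusted p = 0.00208; adjusted p = 0.636 with an estimated correlation). Angptl4 was at -0.66 ± 0.25 in these means, against -1.34 ± 0.25 without irradiation, and neither passed (adjusted p = 1 and 0.811).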

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

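The outlier screen and the difference between gates after irradiation were planned, and the explanations weighed for them were chosen after the results were seen. Dixon's ratio was above its critical value in 15 of 170 series of up to 7 vehicle mice, where 8.5 would be so by chance at 1 in 20. Of single genes, it was 0.609 for Sox9 in unsorted replicate 3 (lowest), 0.651 for Olfm4 in High replicate 3 (lowest), 0.649 for Hopx in Low replicate 3 (highest), 0.569 for Chga in unsorted replicate 5 (highest), 0.585 for Fabp1 in Negative replicate 5 (lowest), 0.582 for Cdkn1a in High replicate 3 (highest), and 0.586 and 0.572 for Igfbp4 in Low replicate 3 (highest) and unsorted replicate 2 (lowest). In Low replicate 3 list means were lowest for G2 and M (0.693), S phase (0.793) and ribosome biogenesis genes (0.574) and highest for enteroendocrine (0.671) and lysosomal genes (0.758). The enteroendocrine mean of Sublow replicate 3 was highest (0.595) and the oxidative phosphorylation mean of Negative replicate 5 lowest (0.696). All these samples stayed in the fits.

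Without irradiation, the Sublow and Low arrays of replicate 3 in the treatment series resembled the next brighter gate, Low and High, while those of irradiated mice matched their own gate. Other arrays matched the next dimmer gate, such as non-irradiated Sublow replicate 2, which matched Negative with vehicle (0.562, against 0.557 with Sublow) and with IGF1 (0.758, against 0.401). A swap of the Low and High labels is excluded, since 0 of 4 High replicate 3 arrays matched the Low profile best. Gates of replicate 3 set at brighter cells would put its Sox9 above both other replicates, and this held in 9 of 12 Sublow, Low and High groups. A slide or hybridisation effect is undecided: the deviation of Low replicate 3 had a mean correlation across genes of 0.445 (SD 0.343 over the 4 treatments) with the High minus Low difference of the second array set. It was 0.736 and 0.724 in non-irradiated vehicle and IGF1 mice and 0.041 and 0.281 in irradiated ones. Among the 48 arrays, 34 matched the profile of their own gate best.

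Irradiated High cells carried more cell cycle transcripts, 4 of 19 active stem cell genes rose, and the effect differed from that in Low cells for 26 genes. Low-like cells admitted to High stay open as a source (rule tightened after the values were seen). On the model of a mix, 68.5% of such cells would be needed for the G2 and M shift and would move the enteroendocrine list by -1.018, while it moved by 0.523 (SD 0.878 over 3 replicates, from -0.364 to 1.392). Against this, 4 of 6 irradiated High arrays matched the Low profile best. Sox9 (-0.76) and enteroendocrine genes (-1.54) fell in High as in Low cells, so neither decides. Normalisation to the reference is excluded for the G2 and M list, since its median was 1.924 (SD 0.38) with the sample channel alone. Replicate 3 alone is excluded as the source of that list's rise, since the median was 1.419 without it (adjusted p = 4.77e-17), although with an estimated correlation and all replicates the list was not called (0.278). The active stem cell call (adjusted p = 0.00092) was lost with fry (0.0639) and with an estimated correlation (0.603). The count of 26 became 1, 0 and 954 without replicate 1, 2 and 3.

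The named genes of that difference were Slc38a5 (2.69), Dll3 (2.401), Bhlha15 (2.16), Il17rb (-2.55), Pax1 (-2.31), Igfbp2 (-2.19), Clec4a1 (-2.17), Slc13a3 (-2.13) and Gstk1 (-2.12). Its described lists had medians of 1.43 for active stem cell, 1.16 for G2 and M, 1.17 for S phase, -0.72 for cholesterol synthesis, 0.52 for enteroendocrine, -0.89 for glycolytic and 2.65 for Paneth genes. The enteroendocrine call (adjusted p = 0.00881) was lost without replicate 3 (0.392), with an estimated correlation (0.825), with fry (0.726) and with scale normalisation. Between the IGF1 effects with and without irradiation 11, 14, 7 and 10 lists were called in High, Low, Sublow and Negative cells, and 9 between the IGF1 effects in High and Low cells, with the preset correlation only.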

How the results depend on the processing

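The alternatives that leave out replicates of every group and those that weight the arrays in list tests were chosen after the first results were seen, and the others were planned. Of 562 alternative counts, 419 moved by no more than 1.5 times and 143 by more. Of 20419 gene values, 19287 were unchanged in call and direction and 11 were reversed, and of 1476 list values 1315 and 2. The treatment groups hold 3 mice, so single libraries decide many calls, and array position is tied to treatment. Leaving out 1 replicate or library gave 12348 to 13490 genes for High minus Low, 3176 to 4856 for Low minus Sublow, 14939 to 16211 for Sublow minus Negative and 9360 to 10770 for sorted minus unsorted. For irradiation it gave 1938 to 7765 in High, 758 to 3054 in Low, 602 to 1736 in Sublow and 3344 to 7801 in Negative cells and 3517 to 7599 in the mouse means.

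The first array set (replicates 1 to 3) alone gave 6990 genes for High minus Low and 12 for Low minus Sublow. It gave 9553 for Sublow minus Negative and 4759 for sorted minus unsorted. Slide as a random block gave 2876 for Low minus Sublow, and the mouse as a random block gave 96 for the irradiation effect in High minus that in Low. Scale normalisation between arrays stretches the arrays of small ratio spread, those of unsorted tissue among them. It gave 4595, 1195, 10674 and 6975 for the 4 gate comparisons, 1023 for irradiation in High, 10 for the irradiation effect in High minus that in Low, 0, 0 and 4 for IGF1 in non-irradiated High, Negative and Sublow cells, and 11 and 2 for IGF1 in irradiated Negative and Sublow cells, and it called 225 of the named genes. Array weights gave 7023 for Low minus Sublow, 10263 and 4750 for irradiation in High and Sublow and 1705 for the irradiation effect in High minus that in Low. For IGF1 without irradiation they gave 626, 16, 2193 and 5 in High, Low, Negative and Sublow cells, with irradiation 1325 and 3 in Negative and Sublow cells, for IGF1 by irradiation 342 in Negative and 1 in Low cells, and 101 for the IGF1 effect in High minus that in Low. List tests called 11 with an estimated correlation and 203 with fry.

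The replicate block, by slide, gave 5969 and 4014 for irradiation in Low and Sublow cells, 496 for the irradiation effect in High minus that in Low, 29, 30 and 1 for IGF1 in non-irradiated High, Negative and Sublow cells, 13 in irradiated Negative cells and 2 for IGF1 by irradiation in Negative cells. No other count moved by more than 1.5 times with it. All 64 sorted arrays in one fit gave 5529, 4532 and 828 for irradiation in Low, in Sublow and in High minus Low, and 52, 1, 296, 3, 13 and 2 for IGF1 in non-irradiated High, Low, Negative and Sublow, irradiated Negative and High minus Low. With array set as a covariate these were 5320, 3991, 1011, 20, 0, 12, 2, 12 and 2 in that order. Only non-irradiated vehicle lay in the second set, so without the covariate set and treatment are tied. A fit of only the populations compared gave 2166 for irradiation in Low, 3 for the irradiation effect in High minus that in Low, and 0 for IGF1 in non-irradiated High and Negative and in irradiated Negative cells. The sample channel alone gave 0, 6 and 38 for these IGF1 comparisons and 1 for IGF1 by irradiation in Negative cells. The scanner's log ratio and the values of the series record each gave 1 and 2 for IGF1 in irradiated High and Negative cells and 9 for the irradiation effect in High minus that in Low. The mean of all probes gave 6 for IGF1 in Negative cells and 1 for the IGF1 effect in High minus that in Low.

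Without replicate 1 of every group, irradiation counts were 2191, 1337 and 602 in High, Low and Sublow cells, 1 for High minus Low and 3517 in the mouse means. Without replicate 2 they were 1938, 758, 1002 and 3344 in High, Low, Sublow and Negative cells, 0 and 4191, and without replicate 3 they were 1404 in Sublow cells, 954 and 5468. IGF1 counts in non-irradiated cells were 1 in High, 1 in Low and 2 in Sublow without replicate 1, 0 in High and 121 in Negative without replicate 2, and 20, 5 and 1 in High, Low and Negative without replicate 3. In irradiated cells they were 1, 30 and 0 in Negative without replicate 1, 2 and 3, and 3 and 1 in High and Low without replicate 3. IGF1 by irradiation gave 5 in Negative without replicate 2 and 1 each in High and Low without replicate 3. Single libraries moved irradiation to 3811, 4031 and 3862 in High (irradiated 1, irradiated 2, non-irradiated 3), 1657 and 2008 in Low (irradiated 2, non-irradiated 3), 1357 and 1423 in Sublow (irradiated 2, non-irradiated 3), 5215 in Negative (non-irradiated 2) and 5030 in the mouse means (irradiated 2). They moved its High minus Low difference to 14, 11 and 13 (High irradiated 1 and 3, non-irradiated 2), 7, 7, 7 and 360 (Low irradiated 1, non-irradiated 1, 2 and 3). For IGF1 they gave 14, 1, 7, 7, 0 and 0 in non-irradiated High (IGF1 1 to 3, vehicle 1 to 3), 7 and 4 in Low (vehicle 1 and 2), 1 in Sublow (vehicle 2), 39, 17 and 747 in Negative (IGF1 1 and 3, vehicle 2), and 9 in the mouse means (vehicle 1). With irradiation they gave 1 in High (vehicle 3), 1 and 1 in Sublow (IGF1 1, vehicle 2) and 1, 53, 7, 1 and 1 in Negative cells (IGF1 1 and 2, vehicle 1 to 3). IGF1 by irradiation in Negative gave 26, 1 and 20 (irradiated IGF1 2, irradiated vehicle 2, non-irradiated vehicle 2), and the IGF1 effect in High minus that in Low gave 1 (IGF1 1).

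Directions of called results (for lists, of the test) were reversed in 13 cases, 12 with scale normalisation, and no reversed value passed. For lists these were active stem cell genes with IGF1 in Low cells at -0.58 with and 0.45 without irradiation. For Low minus Sublow they were Alpi at 0.045, Ascl2 at -0.027, Fabp1 at 1.34, Lrig1 at -0.014 and Smoc2 at -0.17, and for sorted minus unsorted Ascl2 at -0.073, Hopx at -1.62, Lyz1 at -0.68 and Sdhd at 0.15. Gstk1 was at 0.089 for the irradiation effect in High minus that in Low. With the sample channel alone Itln1 was at -0.047 for Low minus Sublow. The cause was not tested. Medians of called lists changed sign, with the direction of the test unchanged, for active stem cell genes after irradiation in Low cells (0.095 with scale normalisation, not called), p53 targets after irradiation in High cells (0.103 with the sample channel alone) and enteroendocrine genes for the irradiation effect in High minus that in Low (-0.152 with array weights). Scale normalisation also removed the calls of the active stem cell, oxidative phosphorylation, Paneth and Wnt lists for Low minus Sublow and of the T cell list for High minus Low. For irradiation it removed those of the enteroendocrine and T cell lists in High and Negative cells, of p53 targets in High, red blood cell genes in Negative and active stem cell genes in Low cells, of T cell genes in the mouse means, and of the S phase and enteroendocrine lists for the effect in High minus that in Low. For IGF1 without irradiation it removed those of heat shock genes in Negative, tuft and active stem cell genes in Low and goblet genes in Sublow cells, and with irradiation those of active stem cell and enteroendocrine genes in Low and of ribosome biogenesis genes in Sublow cells.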

Other observations

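The tests of clock genes described here and the splits that exchange gates within replicate numbers or whole slides were chosen after the results were seen, and the splits into groups of the planned sizes were planned. Lists not described so far also moved after irradiation. Immediate early genes fell in Low cells, 10 of 20 with a median of -1.17 (camera's adjusted p = 3.13e-07), in High cells, 11 with 1 rising (-1.27, 0.00182), and in Sublow cells, 6 with 1 rising (-0.67, 0.00287). Egr1 fell by 2.35 ± 0.54 in Low and by 1.89 ± 0.54 in High cells, where Myc rose by 1.62 ± 0.42. DNA repair genes rose in High cells, 20 of 30 with 1 falling (1.06, 2.2e-11). The counts adjusted over the list alone were 14, 12 and 8 lower immediate early genes and 23 higher DNA repair genes. With an estimated correlation the adjusted p values were 0.35, 0.603, 0.521 and 0.278. The lists and genes of this paragraph and the next were not refitted without single libraries.

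MHC class II genes were lower after irradiation in Sublow cells, and interferon response genes in High and Negative cells. The former fell in 3 of 8 cases with a median of -1.49 (adjusted p = 0.000205; 0.243 with an estimated correlation), with H2-DMa lower by 1.72 ± 0.33 and Cd74 by 1.74 ± 0.50. Of 29 interferon response genes 13 fell and 1 rose in High (-0.63, 0.00781) and likewise 13 and 1 in Negative cells (-0.60, 0.0173), at 0.603 and 0.793 with an estimated correlation. T cell markers fell in both of these gates as well, with medians of -0.99 and -1.89, so a change in lymphocytes was not ruled out. The immunoproteasome genes Psmb8 and Psmb9 fell by 2.22 ± 0.32 and 1.79 ± 0.36 in Negative and by 1.79 ± 0.32 and 1.77 ± 0.36 in Sublow cells. There fell, adjusted over the list alone, 6 MHC class II genes and 14 interferon genes in each of the gates named. FOXO target genes fell in the mouse means, 11 of 20 with 1 rising (-0.74, 0.00598; 0.67 with an estimated correlation). In these means the chemokine Ccl28 fell by 2.41 ± 0.28 and the immunoglobulin receptor Pigr by 2.11 ± 0.24, and the hydroxylase Egln3 rose by 2.58 ± 0.24.

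Of 14 clock genes, Dbp and Arntl passed with IGF1 in Negative cells of non-irradiated mice, and none passed in another gate or in the mouse means (lowest adjusted p = 0.811). The clock score of 14 genes was 0.128 ± 0.076 (SD, n = 3) with vehicle and 0.682 ± 0.188 with IGF1, a difference of 0.554 with an exact two-sided permutation p = 0.1, the smallest possible for 3 against 3. After irradiation it was 0.201 ± 0.08 and 0.388 ± 0.172 (difference 0.187, exact permutation p = 0.2), and over both strata the difference was 0.37 (exact permutation p = 0.01, 400 regroupings). The score holds Dbp and Arntl, whose changes prompted it, so these p values are no independent evidence. The score rose in all 4 populations, by 0.261 at the least, beside an SD of 0.076 over the means of the vehicle mice. The 4 populations come from the same mice and the rule was set after the values were seen, so a gate shift is not excluded. The sample channel alone gave 0.601 (SD 0.059), which argues against a reference effect. Other scalings were untested. Time of day at collection is undecided: 12 of 14 genes moved with their phase, and the sources used here give no hour.

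The same arrays were split into groups of the planned sizes, and the number of splits that called at least as many genes as the real one is given, the real one included. It was 1 of 100 for each of High minus Low, Low minus Sublow, Sublow minus Negative and sorted minus unsorted, with 9858, 505, 13063 and 3404 genes in the highest other split. These splits ignore that gates of 1 replicate number are related. Among 64 splits that exchange neighbouring gates within replicate numbers, 1 called as many in each of the first 3 comparisons, with 10882, 1843 and 13296 in the highest other, which exchanged 1 pair. For irradiation it was 1 of 10 in High, Low, Sublow and Negative cells and in the mouse means, with 0, 26, 0, 2 and 0 genes in the highest other split, and 10 splits are too few to reach 0.05. For IGF1 without irradiation it was 6, 10, 10 and 5 of 10 in High, Low, Sublow and Negative cells, with up to 68, 342, 0 and 3181 genes, and with irradiation 10, 10, 10 and 4 of 10, with up to 2372, 3, 0 and 1236. Over the mouse means it was 10 of 10 without and with irradiation, with up to 0 and 1939 genes. Where it was 10 of 10 the real count was 0, which every split reaches, so the share says nothing. In Negative cells 3 genes were called with IGF1 and 4 in irradiated mice. Splits that exchange vehicle and IGF1 within slides gave up to 101 and 7 there. No split was run with slide as a block, where the counts were 30 and 13, so these calls stay undecided.

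Splits of the contrasts between effects mix irradiated with non-irradiated arrays or High with Low cells, and carry these differences into the counts. It was 100 of 100 splits for the IGF1 by irradiation contrast in High, Low, Sublow and Negative cells, with up to 7101, 3876, 491 and 7749 genes, and 100 for the IGF1 effect in High minus that in Low, with up to 9413. The real counts were 0 in these 5 contrasts, so every split reaches them and the shares say nothing. For the irradiation effect in High minus that in Low 25 of 100 splits called at least 26 genes, with up to 9702. Exchanging whole slides with slide as a block, 1 of 10 splits called at least 496, and the next called 3.

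Heat shock genes of the mouse means differed with IGF1 by -0.543 without irradiation and by -0.166 with it, each at an exact permutation p = 0.2. Lists moved together in other splits as well: for irradiation in High cells 3 of 10 splits called at least the 17 lists of the real one, and for IGF1 in non-irradiated Negative cells 5 of 10 called at least 12, with up to 21.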
